A study of Mus musculus with 9 samples.

How the data were processed

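Gene expression was measured with 1-colour Affymetrix arrays in 9 samples of cultured mouse bone marrow-derived macrophages, with 3 arrays in each of 3 groups. Per the labels' protocols, total RNA was extracted with a spin-column kit, biotinylated cRNA was prepared by the array maker's standard procedure, and each sample was hybridised to its own array. The deposited values are log2 probe-set values that the authors had already normalized between arrays. The log2 scale was read from the values, which run from 5.86 to 14.2, since no header states it. The background correction, normalization, summary method and chip definition are not given in the sources used here. The array medians lay between 7.19 and 7.25, and each sorted column lay within 0.146 of the mean sorted column.

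The table held 17931 probe sets. Of these, 17867 carried a UniGene cluster number, and 64 were the array maker's control sets. For 57 clusters the table held a plus and a minus set, and the set with the higher mean over all 9 arrays was used, which left 17810 clusters. The control sets comprised 19 for mouse transcripts, 18 for hybridization controls of bacterial or phage origin and 27 for bacterial poly-A controls. The last kind ranged from 6.09 to 7.00 and served as a reference for the low end of the scale. The mean of 10768 clusters (60.5%) lay above the highest of these values.

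The files do not pair the cluster numbers with gene names. The gene table used here, of assembly GRCm38.p6, gave a name to 0 of the clusters. The tests of the 35 gene lists fixed in advance, which covered pathways and cell-type markers, were therefore not run. The rule for named genes, also fixed in advance, asked for 11 genes by symbol, among them Ms4a8a, Arg1 and Mrc1. It further asked for the 10 largest rises and falls in each comparison, for the 10 clusters farthest above or below both single arms, and for members of the gene lists. Without names, the symbols could not be looked up. Clusters beyond both arms had to pass the test in both comparisons, without overlap of arrays, and with a higher-group mean above the median. The text gives 2 cluster numbers above and 2 below both single arms, taken from the top of that part of the rule. It also gives the mouse control sets, whose names in the file include the transcript and which were chosen after the table was seen.

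Differences between groups were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a mean-variance trend on the deposited log2 values. All 9 arrays entered one model with group as its only term, which left 6 residual degrees of freedom and gave 3.85 prior degrees of freedom. The p-values were adjusted with the Benjamini-Hochberg method over 17829 features, that is the clusters and the mouse control sets, with a threshold of 0.05. Counts of changed genes are over the 17810 clusters, and a further count asks for a change of at least 2-fold. No filter on dim probe sets was applied. Quantile normalization had been planned if medians or quantiles of the arrays differed, with no size fixed for such a difference. The differences given above were small, so the values were kept as deposited and quantile normalization was run as an alternative. Single values per array were compared with exact two-sided permutation tests, whose smallest possible p with 3 arrays against 3 is 0.1.

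The procedure was tested on simulated data for the 17829 features, with 200 clusters changed in the combination. In the comparison with dexa+IL4, 98.5% of the changes of 0.5 on the log2 scale and 100% of those of 1 and 2 were recovered. In the comparison with cmB16F1 the shares were 95.5% and 100%. Each of these comparisons called 13 clusters that had not been changed, and the comparison of the single arms called 0. The simulated noise was independent normal noise of the size limma had estimated, equal in all groups. In the real data the SD over probe sets of the difference between 2 arrays was 0.077 to 0.109 within dexa+IL4. Within the combination it was 0.146 to 0.163. Deviations shared between arrays were not simulated either, so these shares may be too favourable for the real data.

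The labels number the arrays of each group 1 to 3 without saying whether equal numbers share a culture or an animal. Deviations from the group means were correlated across clusters for arrays of equal number. Between the combination and cmB16F1 the correlations were 0.617, 0.565 and 0.662, all over the limit of 0.1 fixed for pairing, so the numbers were taken to pair these groups. The model without a block, fixed before the data were examined, still gives the counts in the text, and, for results that rest on the comparison of these groups, values with the replicate number as a block stand beside them where the block changed a call or moved a count by over 1.5 times. For the comparisons not taken as paired, the effect of the block is given only in the closing section. For the combination and dexa+IL4 they were 0.224, -0.0672 and 0.116. For dexa+IL4 and cmB16F1 they were 0.236, -0.0234 and 0.167, so neither of these comparisons was taken as paired. This check was computed in the same run as the fits with a replicate block, not ahead of them.

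The alternatives planned before the data were examined were quantile normalization, median centring, leaving out the dimmest 30% of clusters, the mean of the probe sets of a cluster, eBayes without a trend, array weights, only the arrays of the groups compared, the replicate number as a block, and leaving out each array in turn. Scaling each array to its hybridization controls was added after the data were seen, as was an exact two-sided sign-flip test of the quality measures over the 3 pairs of combination and cmB16F1 arrays. Where a group's mean lay within the range of the bacterial controls, a fold against it is a lower bound, taken against the higher of the probe set's value and the highest bacterial control on each array of that group. For clusters called in both comparisons of the combination, which share its arrays, 100 data sets with unchanged groups were simulated. The labels do not say that the replicates came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision, and the median standard error of a difference was 0.0500 on the log2 scale.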

Results

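Bone marrow cells of C57BL/6 mice were grown with macrophage colony-stimulating factor (M-CSF) at 30 ng/ml and stimulated from day 4 for 3 days. The first group received dexamethasone, a synthetic glucocorticoid, at 5e-07 M and interleukin 4 (IL-4) at 10 ng/ml (dexa+IL4). The second received medium conditioned by B16F1 cells, a mouse melanoma line (cmB16F1). The third received both (cmB16F1+dexa+IL4, here the combination). Each group had 3 arrays, and 17810 UniGene clusters were measured on each. The series title asks about joint action of these signals and about Ms4a8a, a relative of CD20. The files do not pair cluster numbers with gene names, so the level of Ms4a8a is not reported. No arrays of medium alone were used here, so neither synergy nor additivity was tested. The genes named in the text are those of the array maker's mouse control sets, most of which probe the 3' end, the 5' end and the middle of a transcript.

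The 3 groups were separated. The first principal component held 56.6% of the variance and placed the combination, at -3.15 ± 3.28 (SD, n = 3), between dexa+IL4 at -21.2 ± 1.0 and cmB16F1 at 24.4 ± 2.63. The second component held 28.1% and set the combination, at 18.2 ± 5.13, apart from dexa+IL4 at -10.6 ± 2.14 and cmB16F1 at -7.63 ± 3.60. Across clusters, Pearson correlations ran from 0.991 to 0.998 between arrays of one group and from 0.947 to 0.983 between arrays of different groups, where clusters are not independent replicates.

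**Figure D1:**
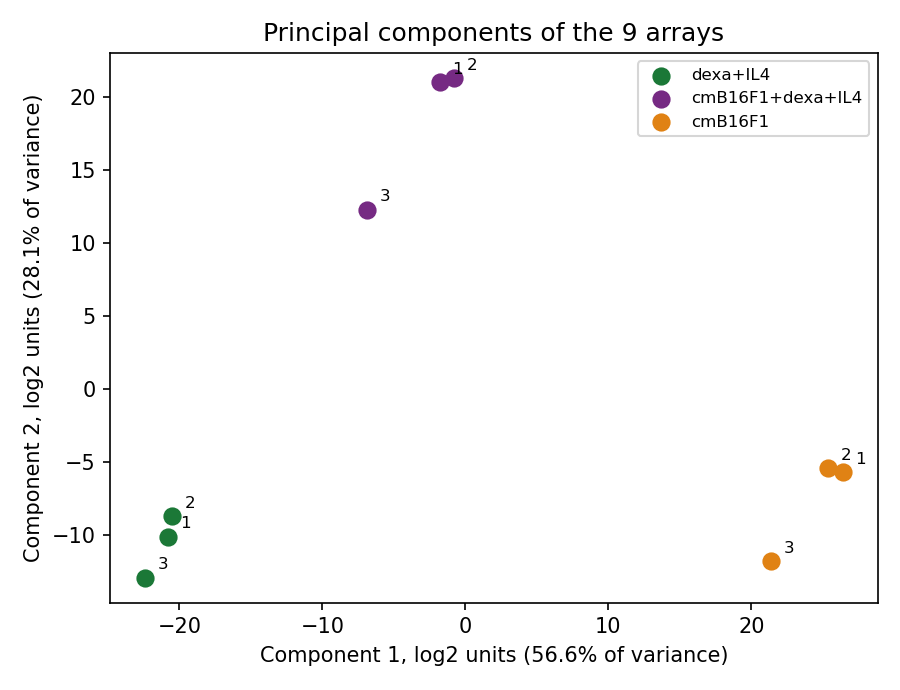
Principal components of the 9 arrays, with the first component (log2 units, 56.6% of the variance) on the horizontal axis and the second (log2 units, 28.1%) on the vertical axis. Each point is an array, coloured by group and numbered by replicate. The combination lies between the single arms on the first component and above both on the second, where its replicate 3, at 12.3, is its lowest array.

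The first comparison asked what conditioned medium changed in cells that also received dexamethasone and IL-4. Transferrin receptor, which takes up transferrin-bound iron, fell by 1.84 on the log2 scale at its 3' set, to 8.65 ± 0.19 (SD, n = 3) in the combination from 10.49 ± 0.15 in dexa+IL4. Gapdh, a glycolytic enzyme, was 1.54-fold higher at its 3' set, with 12.85 ± 0.12 against 12.23 ± 0.04. The cytoskeletal gene beta-actin, at 13.74 ± 0.04 against 13.68 ± 0.09, did not pass the test. Cluster Mm.154144 rose from 10.77 ± 0.47 to 13.93 ± 0.005, so close to the highest value of any array, 14.2, that the size of its rise is uncertain and no fold is given. Cluster Mm.34460 rose 8.06-fold, from 7.76 ± 0.13 to 10.77 ± 0.16.

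For the transferrin receptor the limma log2 fold change was -1.84 at the 3' set (SE 0.0987, Benjamini-Hochberg adjusted p = 5.917e-06). Its 5' and middle sets also fell, with changes of -1.59 and -1.63. In each of these sets all 3 combination arrays lay below all 3 dexa+IL4 arrays. The Gapdh change was 0.62 at the 3' set (limma adjusted p = 1.842e-04), 0.48 at the 5' set (0.0219) and 0.63 at the middle set (3.965e-04). The 5' Gapdh call was lost with scaling to the hybridization controls and without dexa+IL4 replicate 1 or 3 or combination replicate 1 or 2, with limma adjusted p between 9.223e-04 and 0.115 over 18 alternatives. Both 3' beta-actin means lay near the highest value of any array, 14.2, where a change may be compressed. The 3' beta-actin change was 0.06 with a 95% confidence interval from -0.06 to 0.18 (limma adjusted p = 0.526), and -0.20 with scaling to the hybridization controls. Its 5' and middle sets, at -0.10 and -0.01, missed the threshold as well (limma adjusted p = 0.738 and 0.981), and the 5' set passed with that scaling. Pyruvate carboxylase, which feeds oxaloacetate to the citric acid cycle, passed the test at none of its 4 sets, whose changes ran from -0.08 at the 5' set to -0.002 at the first middle set. Over all 3 groups its means ran from 7.14 to 7.50, little above the highest bacterial control, 7.00, so its changes may be too small. The 5' set passed with quantile normalization and with scaling to the hybridization controls, and the second middle set with the latter. The 3' set of 18S ribosomal RNA was at 9.94 ± 0.53 in the combination and 9.21 ± 0.07 in dexa+IL4 (change 0.73, limma adjusted p = 0.152), and it passed the test under 2 of 18 alternatives, 1 of them scaling to the hybridization controls. That change was 0.48 without combination replicate 3 and larger than in the main fit without its replicate 1. The 5' and middle 18S sets, at 0.60 and 0.68, missed the threshold too (limma adjusted p = 0.221 and 0.0993), and passed under 1 and 5 of 18 alternatives.

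In all, 3184 clusters (17.9%) differed, of which 1581 were higher and 1603 lower in the combination. The median size of their change was 0.32 on the log2 scale. A change of at least 2-fold was found for 119 higher and 65 lower clusters. The arrays of the groups did not overlap in 6438 clusters (36.1%), against 10% by chance. Without dexa+IL4 replicate 1 the count was 2044, and without its replicate 3 it was 2096. The share of higher clusters among those called, 49.7%, was 38.1% with median centring and 5.34% when arrays were scaled to their hybridization controls, an alternative chosen after seeing the data that shifted the median change to -0.26.

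The second comparison asked what dexamethasone and IL-4 changed in cells that also received conditioned medium. Transferrin receptor was 2.85-fold higher in the combination at its 3' set, where cmB16F1 was at 7.14 ± 0.05 (SD, n = 3). That mean lay little above the highest bacterial control, 7.00, so the fold may be too small. Gapdh was 1.22-fold lower at its 3' set, with cmB16F1 at 13.14 ± 0.06. Beta-actin was 1.16-fold lower at its 3' set, with cmB16F1 at 13.95 ± 0.05. That is so close to the highest value of any array, 14.2, that the size of this change is uncertain. Clusters Mm.154144 and Mm.34460 also rose, from 6.94 ± 0.25 and 6.80 ± 0.07. Both of these means lay within the range of the bacterial poly-A controls, 6.09 to 7.00, and are not told apart from background. Against the highest bacterial control of each array, where that was above the cluster's own value, Mm.154144 was at least 119-fold and Mm.34460 at least 14.1-fold higher in the combination.

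The transferrin receptor change was 1.51 at the 3' set (SE 0.0987, limma with Benjamini-Hochberg adjusted p = 6.338e-06). Its 5' and middle sets rose too, with all 3 combination arrays above all 3 cmB16F1 arrays in each set. In cmB16F1 these sets, at 6.47 ± 0.03 and 6.57 ± 0.05 (SD, n = 3), were also within the range of the bacterial controls, so that they were at least 1.20-fold and 1.47-fold higher in the combination. The Gapdh change was -0.29 at the 3' set (limma adjusted p = 0.0124) and -0.34 at the middle set (0.0126). The 3' call was lost without cmB16F1 replicate 2, with limma adjusted p between 7.231e-04 and 0.0524 over 18 alternatives. The 5' Gapdh set, at -0.32, missed the threshold (limma adjusted p = 0.125) and passed it with the replicate number as a block (0.00869), with scaling to the hybridization controls and without combination replicate 1, within a range from 5.911e-04 to 0.330 over 18 alternatives. The 3' beta-actin change was -0.21 (limma adjusted p = 0.0237), and its call was lost with array weights and without cmB16F1 replicate 1 or combination replicate 2, with adjusted p between 0.00168 and 0.0872 over 18 alternatives. The middle beta-actin set, at -0.34, missed the threshold (limma adjusted p = 0.0912) and passed it with the replicate block (0.0299) and with scaling to the hybridization controls, within a range from 8.886e-05 to 0.266 over 18 alternatives. The 5' beta-actin set, at -0.40, missed the threshold (limma adjusted p = 0.143) and passed it with scaling to the hybridization controls. The 18S sets, with changes between -0.03 and 0.05, did not pass. None of the 4 pyruvate carboxylase sets passed, with changes between 0.02 and 0.08 that turned negative with scaling to the hybridization controls.

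In this comparison 2516 clusters (14.1%) differed, 1168 of them higher and 1348 lower in the combination. Changes of at least 2-fold numbered 108 upward and 120 downward. The median size of a called change was 0.34. The groups did not overlap in 5076 clusters (28.5%), against 10% by chance. The share of higher clusters among those called, 46.4%, was 11.7% with scaling to the hybridization controls, which shifted the median change to -0.20.

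The third comparison set the single arms against each other, and since they differ in every agent it singles out none. Transferrin receptor was 10.2-fold higher in dexa+IL4 than in cmB16F1 at its 3' set, at least 3.61-fold at its 5' set and at least 4.57-fold at its middle set. The 3' set, at 7.14 in cmB16F1, lay little above the highest bacterial control, 7.00, so the 10.2-fold may be too small. Gapdh was 1.89-fold lower in dexa+IL4 at its 3' set and 1.96-fold lower at its middle set. Beta-actin was 1.20-fold lower at its 3' set, a size that is uncertain since cmB16F1, at 13.95, lay near the highest value of any array, 14.2. Cluster Mm.154144 was at least 13.3-fold higher in dexa+IL4, and Mm.34460 at least 1.75-fold. The bounds are taken, as above, against the bacterial controls, since the cmB16F1 means lay within their range.

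The 3' transferrin receptor change was 3.35 (SE 0.0987, limma with Benjamini-Hochberg adjusted p = 2.791e-08) and the 3' Gapdh change -0.92 (SE 0.0640, adjusted p = 6.122e-06), with no overlap of the groups in either. The 5' Gapdh change was -0.80 (limma adjusted p = 9.375e-04). The 3' beta-actin change was -0.27 (limma adjusted p = 0.00433), and its call was lost with scaling to the hybridization controls, where adjusted p was 0.245, the highest of 18 alternatives from 0.00320 upward. Its 5' and middle sets, at -0.30 and -0.34, missed the threshold (limma adjusted p = 0.207 and 0.0655), and the middle set passed under 1 of 18 alternatives. The pyruvate carboxylase sets lay near the bacterial controls, as given above. Of these, the 5' set passed at 0.11 (limma adjusted p = 0.0315), a call lost under 6 of 18 alternatives, with adjusted p from 0.0167 to 0.703. The 6 were scaling to the hybridization controls and leaving out dexa+IL4 replicate 1, 2 or 3 or cmB16F1 replicate 1 or 2. The second middle set of pyruvate carboxylase missed the threshold but passed with quantile normalization and with median centring. Its 3' set also missed the threshold and passed with median centring. The 3' set of 18S ribosomal RNA was at 9.97 ± 0.68 (SD, n = 3) in cmB16F1, and its change of -0.76 missed the threshold (limma adjusted p = 0.116). It passed under 4 of 18 alternatives, with adjusted p from 3.167e-05 to 0.345 over the 18, and was -1.12 without cmB16F1 replicate 1 and -0.45 without its replicate 2. The 5' and middle 18S sets, at -0.57 and -0.63, missed the threshold too (limma adjusted p = 0.218 and 0.105), and passed under 1 and 4 of 18 alternatives. Of the 3 sets for B1 and B2 repeats, short interspersed elements, none passed in any of the 3 comparisons.

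Between the single arms 4454 clusters (25%) differed, 2273 of them higher and 2181 lower in dexa+IL4. At least 2-fold changes numbered 145 upward and 237 downward. The groups did not overlap in 7898 clusters (44.3%), against 10% by chance. With scaling to the hybridization controls 1893 clusters passed, though the share of higher clusters among those called hardly moved, from 51.0% to 49.3%.

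**Figure D2:**
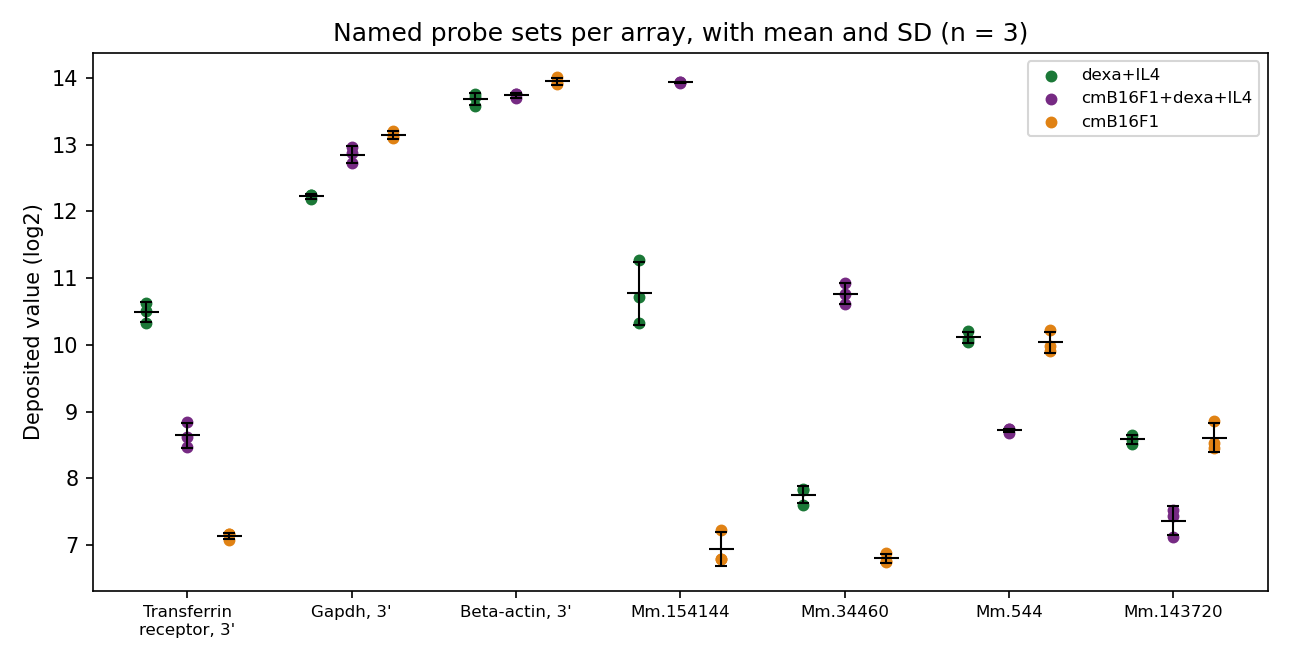
Deposited log2 values (vertical axis) of 7 probe sets on each of the 9 arrays. Points are arrays coloured by group, and black bars give the mean and SD (n = 3). Transferrin receptor falls from 10.49 in dexa+IL4 through 8.65 in the combination to 7.14 in cmB16F1, Gapdh goes the other way, Mm.154144 and Mm.34460 are highest in the combination, and Mm.544 and Mm.143720 are lowest there.

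The design also asks which genes the combination moved beyond both single arms. Mm.154144 and Mm.34460, given above, lay farthest above both. Cluster Mm.544 was lowest in the combination, at 8.72 ± 0.03 (SD, n = 3) against 10.12 ± 0.08 in dexa+IL4 and 10.04 ± 0.16 in cmB16F1, which is 2.63-fold and 2.50-fold lower. Cluster Mm.143720 was at 7.37 ± 0.22 in the combination against 8.58 ± 0.07 and 8.61 ± 0.21, or 2.33-fold and 2.37-fold lower. All 3 combination arrays lay beyond all 6 others in each of these 4 clusters. That, and passing the test in both comparisons, were conditions of their choice and are no further evidence.

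Mm.154144 passed the test against dexa+IL4 and against cmB16F1 (limma with Benjamini-Hochberg adjusted p = 1.447e-05 and 3.596e-08), with the limits on its size given above. The change of Mm.34460 was 3.01 against dexa+IL4 and at least 3.82 against cmB16F1 (limma adjusted p = 1.447e-07 and 4.876e-09). The change of Mm.544 was -1.40 and -1.32 (limma adjusted p = 8.816e-06 and 4.202e-06), while the single arms differed by 0.08 with a 95% confidence interval from -0.10 to 0.26. The change of Mm.143720 was -1.22 and -1.25 (limma adjusted p = 1.541e-04 and 8.093e-05), and its single arms differed by -0.03 with an interval from -0.30 to 0.24. These 8 calls passed the threshold under all 18 alternatives.

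In total 376 clusters were higher in the combination than in both single arms, and 335 were lower. Independent lists of the same lengths would share 104 and 121, a comparison that leaves out the combination arrays both lists share. The simulations with unchanged groups gave 0 on average for each, but with no change the adjusted threshold calls almost nothing, so that value is no baseline for lists of this length. The combination arrays are too few to be split, and part of the excess may come from sharing them. Nor are such counts particular to the combination. A split with all dexa+IL4 arrays in its place gave 608 clusters above and 549 below both other groups. Splits with all cmB16F1 arrays there gave 904 and 682, 520 and 319, and 517 and 318. The remaining arrays may have been regrouped in these splits. The combination with the remaining arrays regrouped gave 71 and 33. At least 2-fold differences from both arms were found for 25 clusters above and 4 below, and the 4 became 12 without combination replicate 3. Without dexa+IL4 replicate 1 the count of lower clusters was 220, and with the replicate number as a block it was 514. Of the 376 and 335 clusters, 298 and 242 were still called with only the arrays of the groups compared. With scaling to the hybridization controls 82 clusters were higher and 988 lower than in both arms, and 29 were at least 2-fold lower. The log2 fold changes of the combination against its single arms correlated at 0.194 across clusters, against 0.499 in simulated unchanged groups. Their covariance was 0.0141 against 0.00237, a difference of 0.0117. In the simulation the single arms did not differ, while the real ones did in 4454 clusters. The simulated values are therefore no baseline for joint change.

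**Figure D3:**
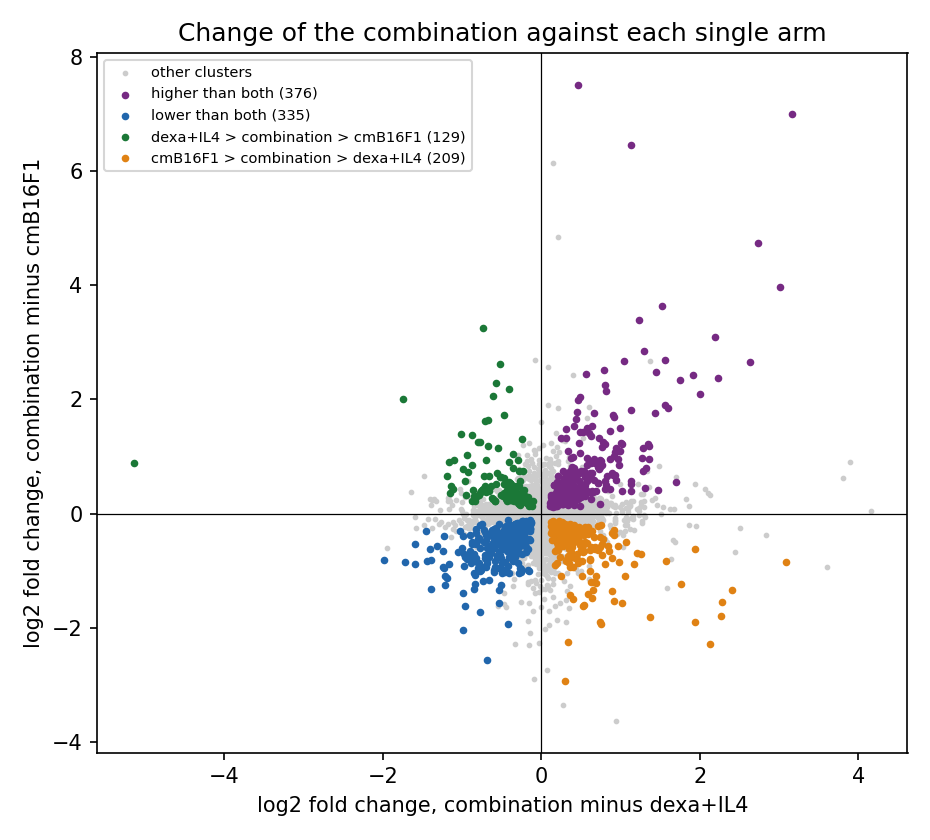
Log2 fold change of the combination against cmB16F1 (vertical axis) plotted against its log2 fold change against dexa+IL4 (horizontal axis) for 17810 clusters, 1 point each. Colours mark clusters past the limma threshold in both comparisons, of which 376 were higher than both single arms, 335 lower than both, 129 between them with dexa+IL4 highest and 209 between them with cmB16F1 highest.

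Measures of RNA and hybridization quality were compared as well. The 3' beta-actin set lay near the highest value of any array, 14.2, and was brightest in cmB16F1. Its difference from the 5' set may therefore be too small, most of all in that group. The 3' minus 5' difference of beta-actin was 0.99 ± 0.11 in dexa+IL4, 1.15 ± 0.22 in the combination and 0.96 ± 0.21 in cmB16F1 on the log2 scale (SD, n = 3; exact permutation p from 0.3 to 1). That of Gapdh was 0.30 ± 0.08, 0.45 ± 0.19 and 0.42 ± 0.20 (exact permutation p from 0.4 to 0.7). Between same-numbered arrays of the combination and cmB16F1, the difference was larger in the combination in 3 of 3 pairs for both genes, by 0.08 to 0.26 for beta-actin and by 0.02 to 0.04 for Gapdh. The exact sign-flip permutation p, a test made after the data were seen, was 0.25 for each, the smallest that 3 pairs can give. The hybridization controls averaged 10.39 ± 0.14 in the combination, above 10.14 ± 0.10 in dexa+IL4 and 10.18 ± 0.14 in cmB16F1. All 3 combination arrays were above all arrays of the other groups, at exact permutation p = 0.1 in each comparison, the smallest that 3 arrays against 3 can give. Against the same-numbered cmB16F1 array the combination was higher by 0.29, 0.32 and, for replicate 3, only 0.03 (exact sign-flip permutation p = 0.25).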

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

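Scaling to the hybridization controls, the block fit on 6 arrays and the graded counts were chosen after seeing the data. Of 194 counts under settings other than leaving out an array, 177 stayed within 1.5 times. Of 1242 values of the named probe sets, 1195 stayed on their side of the threshold, 16 fell below it, 31 newly passed, and 0 called values changed sign. With the replicate number as a block, 514 clusters instead of 335 were lower than in both single arms and 203 instead of 129 were graded with dexa+IL4 highest, and the cause was not tested. The block gave 4149, 3052 and 5172 changed clusters for the 3 comparisons (3677 for the second on its 6 arrays). It added calls for 5' Gapdh, middle beta-actin and the 3' and middle 18S sets and changed no other named call.

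Scaling to the hybridization controls shifts every cluster of an array alike, which by construction moves the split of directions where the controls of the groups differ. Between the single arms the controls differed by only -0.04, and the share of higher clusters among those called went from 51.0% to 49.3%. The controls also varied between arrays of a group, so the scaling can end calls through a larger error. It gave 7104 clusters for the combination against dexa+IL4 (379 higher, 6725 lower; at least 2-fold, 78 and 176), 263 higher and 221 at least 2-fold lower against cmB16F1, and 1893 between the single arms (933 and 960). It left 82 clusters above and 988 below both arms, 29 of those below at least 2-fold, and 69 and 97 graded. Of the 376 and 335 clusters beyond both arms, 74 and 325 were still called.

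Leaving out 1 array, with fewer samples, gave 2044 to 3356 clusters for the combination against dexa+IL4 (987 to 1716 higher, 1057 to 1647 lower), 1937 to 2318 against cmB16F1 and 3218 to 4721 between the single arms. It gave 261 to 388 above and 220 to 386 below both arms, 3 to 12 at least 2-fold below, and 80 to 117 and 135 to 211 graded. The lowest of the first, of those beyond both arms and of the graded counts came without dexa+IL4 replicate 1 (2096 for the first without its replicate 3), and 12 came without combination replicate 3. The planned gene-list alternatives were not run, since no cluster had a gene name. Signal over background limits the 39.5% of clusters whose mean lay within or below the bacterial controls.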

Other observations

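Tests chosen after their results were seen were those of mixed RNA, of processing shared by all arrays of a number and of array scaling, along with the counts of clusters between the single arms. Transferrin receptor and Gapdh both lay between the single arms in the combination, in opposite directions. The same held past the limma threshold in both comparisons for 129 clusters in the order of the transferrin receptor and for 209 in the order of Gapdh, where independent lists, which leave out the shared combination arrays, would share 105 and 120. The 129 became 80 without dexa+IL4 replicate 1 and 83 without cmB16F1 replicate 2, and 203 with the replicate block. The 209 became 135 and 136 without dexa+IL4 replicates 1 and 3. For each combination array, the median position on the log2 distance from cmB16F1 to dexa+IL4 was taken over the 382 clusters at least 2-fold apart between the single arms. These array medians averaged 0.577 ± 0.055 (SD, n = 3), which does not measure the spread between clusters.

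Among the 57 clusters with a plus and a minus set, the sets differed in mean level by a median of 0.32, and by over 1 in 7 clusters. Both sets were called in 1 cluster for the combination against dexa+IL4, in 0 against cmB16F1 and in 3 between the single arms, in the same direction each time. Only 1 of the pair was called in 12, 9 and 16 clusters.

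The first pattern weighed was the set of clusters above both single arms. The hybridization controls were brighter on the combination arrays, and a scaling error by the authors' normalization is a candidate explanation. With scaling to these controls, 18 clusters instead of 25 were at least 2-fold above both arms. The 25 need a shift of at least 1 on the log2 scale, a bound that their 2-fold filter set in advance. The controls differed by at most 0.256 (SE 0.0994), so a shift of that size would cover only part of these changes. The filter and the controls already seen fixed this outcome, so the test gives no verdict on scaling. That test replaced an undecided one, whose median smaller change after scaling less its SD over clusters was 0.63 against a bound of 0.76, and one on calls after scaling, whose outcome was largely fixed by how the 25 were chosen. Of the 351 smaller ones only 49 were still called, as the median smaller change went from 0.30 to 0.06 and its median standard error from 0.0594 to 0.136, so scaling may account for many of these, though the larger error also ended calls. Whether the controls or the deposited values are nearer the true level, and whether joint action of the agents raised these clusters, stays open.

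The second pattern was the intermediate position of the combination, for which a mixture of RNA from the single arms is a candidate explanation. A mixture cannot lie outside both of its sources, yet 29 clusters lay at least 2-fold above or below both and passed the threshold in both comparisons. The linear share of dexa+IL4 that would give the combination's level also ran from 0.237 to 0.922 between quartiles over the 382 clusters, where a mixture needs 1 share. Both values argue against mixing as the whole cause, and the graded response of cells to the agents together stays an untested alternative.

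The third pattern was that same-numbered arrays of the combination and of cmB16F1 deviated together. Conditioned medium of differing strength is a candidate explanation, since both groups received it. For each number the deviations of both arrays had the same sign of correlation, across clusters, with the change that conditioned medium brought to dexa+IL4, reaching -0.471 in the combination and -0.369 in cmB16F1 for replicate 3, which met what had been written before as its sign. The dexa+IL4 arrays, which received no such medium, nevertheless had the same signs, with -0.288 for replicate 3, so the result was read as undecided after those values were seen. Processing shared by all arrays of a number needs the dexa+IL4 arrays to deviate with the others, and their correlations with same-numbered arrays ran from -0.0672 to 0.236, which neither excludes nor bears out that explanation. The 3' minus 5' difference of Gapdh also went with the numbers. For replicates 1, 2 and 3 it was 0.24, 0.59 and 0.52 in the combination and 0.19, 0.57 and 0.50 in cmB16F1. In dexa+IL4 it was 0.26, 0.26 and 0.40. Whether RNA quality shared by the pairs underlies their deviations was not tested.

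Other splits of the arrays were tested for each count. For the 3 pairwise comparisons the 6 arrays allow 10 splits, too few for a share under 0.05, and 1 split, the real one, reached the real count in each. The real counts were 3184, 2516 and 4454, and the highest of the other splits gave 0, 1 and 0. For the combination and cmB16F1, whose numbers pair the arrays, the 3 other splits that part all 3 pairs gave 0 clusters in the limma fit, and the 6 that part 1 pair at most 1. All these other splits mix both groups, so the real difference enters the spread within groups and few calls can pass. Their low counts are therefore no baseline for the real ones. Among 100 splits of the 9 arrays into 3 groups, 5 gave at least the 376 clusters above both other groups, the highest other giving 904. That reached the 5 of 100 written before as the sign of chance. For the 335 clusters below both, 3 of 100 gave as many, under that limit, the highest other giving 682. All 5 and all 3 of these splits, the real one among them, put a whole real group in the place of the combination, so they hold real group differences and mainly count how often an intact group was drawn. They say little about chance either way. The 904 and 682 came with all cmB16F1 arrays in that place, so counts of this size are not particular to the combination. Splits without a whole group in that place gave at most 1 cluster above and 0 below. They mix real groups, which widens the spread within groups, so these low counts are no baseline either.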
